A study of Mus musculus with 3 samples.

How the data were processed

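Total RNA from sorted, GFP-positive G1ME cells was measured on 3 Affymetrix mouse expression arrays, 1 per replicate, 42 hours after a retroviral vector encoding GATA1s was introduced. The values are deposited log2 expression values, 1 per probe set, which the authors made with RMA in the affy package, per the submitters' processing notes. RMA subtracts background, quantile normalizes the arrays and summarises the probes of each set, so that differences of dim probe sets are compressed and each array has nearly the same distribution. The versions, the probe definition file and the set of arrays that were normalized together are not given in the sources used here. That the scale is log2 was taken from the values, which lay between 2.35 and 14.54. The same 3 arrays stood in 2 deposited tables, and 0 of 45101 probe sets differed between them, so the second table is no independent alternative.

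All 3 samples form 1 group. The series sets GATA1s against full-length GATA1, but 3 further columns of per-sample values, of arrays from another series, were not used, and a planned limma fit of that comparison was therefore not made. No value reported here is a difference between the isoforms.

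Probe sets were named through a platform annotation table. It gave 34958 probe sets 1 gene symbol, 932 several symbols and 9211 none. Of the 34958, 34754 had an Entrez ID in a RefSeq gene table, and 0 symbols changed through it. Probe sets with several symbols were left out, which removes some near-identical genes such as globin copies. Each of 18194 genes was represented by its probe set with the highest mean over the 3 arrays. Probe sets differ in affinity, so a level was never read as more or less RNA than that of another gene. No coordinates are given, because no genome build is named in the sources used here.

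Values are the mean ± SD over 3 arrays. RMA values carry no detection call, so a floor was taken from 53 genes of non-blood tissues (48 measured): the 95th percentile of their probe sets on each array. A gene was called above the floor if it exceeded it on each of the 3 arrays. The spread between replicates was given as the SD, the pairwise Pearson correlation and the number of probe sets with a range over 1 log2 unit. For each gene list, the median deviation of its members above the floor from their own mean over the arrays was set against 10000 random lists of the same size, drawn within 20 bins of mean level. That percentile describes these arrays and is no test between groups. Random lists do not carry the correlation between genes of 1 pathway, which widens the spread of a real list.

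The list test was run on simulated arrays with the real means and SDs of 7863 genes and lists of 15 genes. Of 100 unshifted lists, 1% lay among the outermost 1% of random lists. A shift of 0.1 log2 in 1 array was found in 68% of lists and a shift of 0.2 in 100%. The simulated genes varied independently and the lists were drawn at random, so the 1% was fixed by the setting. None of these shares need hold for lists of genes that vary together.

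The 17 gene lists, the background list, the floor and the rule for named genes were fixed before the data were examined. The rule names Gata1 first, then up to 4 members above the floor with the highest mean per list (up to 2 for lists of other cell types), then the 10 genes above the floor with the largest range. Other members, among them all that lay below the floor, were named after their values were seen. Alternatives were the other table, each replicate left out, the median over probe sets, floors at the 90th and 99th percentile, no filter on dim genes, renewed quantile normalization and another range limit. In the lists of the closing section, 1 wrong synonym match was corrected after their results had been seen, and tests of array scaling were dropped, because earlier quantile normalization fixed their outcome. The rule for which other probe sets of a gene count was also changed then, from above the floor on each array to a mean above it. Members of the lists fixed earlier were left out of those lists. Calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. The number of arrays limits the precision of every value, and the labels do not say whether the replicates were separate transductions.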

Results

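Expression was profiled in G1ME cells, an immortalized mouse line of bipotent megakaryocyte-erythroid progenitors. They were made from embryonic stem cells without a functional Gata1 gene and are arrested in differentiation until GATA1 is restored. The cells had received GATA1s, the form of the transcription factor that lacks the amino-terminal part, and were kept in thrombopoietin and erythropoietin until they were sorted at 42 hours. The group held 3 arrays. The series was designed to set this short form against full-length GATA1, and the arrays of the full-length form were not analysed here. The account below therefore gives the levels in GATA1s cells and the error behind them. The array medians were 5.20, 5.19 and 5.18 log2 units in replicates 1, 2 and 3, and the background floors were 6.92, 6.78 and 6.92. Of 18194 genes, 7863 lay above the floor on each of the 3 arrays.

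The first question was whether the transduced gene and its known partners gave signal. Gata1 was above the floor on all arrays, at 10.81 ± 0.10 (SD, n = 3). Its single probe set is not tied here to a part of the transcript, so this value does not tell the short form from the full-length one. All 14 measured genes of the GATA1 partner list, which includes Gata1 itself, were above the floor. Among them were Tal1 at 12.14 ± 0.05 and Lmo2 at 11.67 ± 0.11, members of the complex that binds DNA with GATA1. Nfe2, a factor of late megakaryocyte and erythroid genes, was at 12.32 ± 0.06, and Fli1, an ETS factor of the megakaryocyte lineage, was at 11.46 ± 0.33. Zfpm1, the cofactor also called FOG1, was at 11.11 ± 0.19. Gata2, the progenitor GATA factor, was at 9.85 ± 0.07. The erythroid factor Klf1 was at 10.08 ± 0.31.

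Genes of the megakaryocyte and platelet lineage gave signal almost throughout. Of 26 measured members, 24 were above the floor on each array, and the counts on the single arrays were 24, 25 and 24. Pf4, a chemokine stored in platelet granules, was at 13.89 ± 0.04. Plek, a protein kinase C substrate of platelets, was at 12.94 ± 0.08, and Tubb1, the platelet beta-tubulin, was at 12.89 ± 0.12. Thbs1, which encodes the granule protein thrombospondin, was at 12.78 ± 0.28. The integrin chains Itga2b and Itgb3, which form the fibrinogen receptor, were at 12.05 ± 0.17 and 12.14 ± 0.16. The chains of the von Willebrand factor receptor gave 12.15 ± 0.17 for Gp1bb, 11.10 ± 0.04 for Gp9 and 8.50 ± 0.63 for Gp5. The members below the floor on at least 1 array were Selp, at 6.92 ± 0.21, and Itga2, at 4.79 ± 0.03.

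Erythroid genes were divided. Of 22 measured members, 13 were above the floor on each array, with 14, 14 and 15 on the single arrays. The 13 included Gata1, the transduced gene. Car2, a carbonic anhydrase, was at 13.27 ± 0.02, Cited2, a transcriptional coregulator, at 13.03 ± 0.09, and Gypc, a membrane glycophorin, at 10.54 ± 0.03. Epor, the erythropoietin receptor, was at 8.86 ± 0.09. Genes of the red cell membrane and its skeleton lay on both sides of the floor. Above it were Epb42 at 8.26 ± 0.12, Sptb at 7.96 ± 0.13, Kel at 7.79 ± 0.17, Icam4 at 7.36 ± 0.46 and Ank1 at 7.01 ± 0.09. Below it were Slc4a1, the anion exchanger band 3, at 4.89 ± 0.10, Rhag at 4.28 ± 0.73 and Aqp1 at 3.71 ± 0.16. The share of members above the floor was 59.1% for the erythroid list and 92.3% for the megakaryocyte list. That difference was not tested, since both lists were picked by hand and probe sets differ in affinity. With the floor at the 99th percentile of the background list, 6 erythroid genes were above it.

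**Figure D1:**
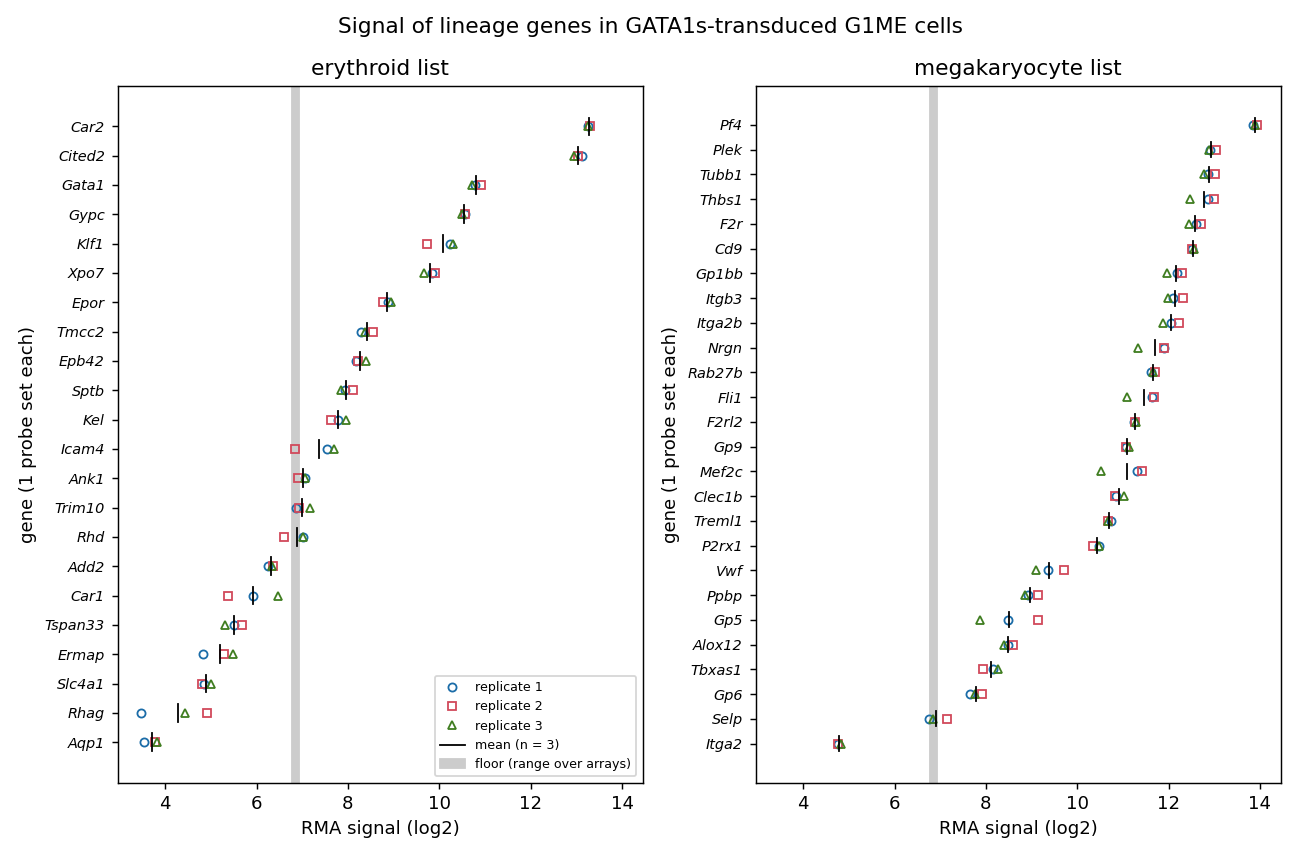
RMA signal in log2 units (horizontal axis) of the measured members of the erythroid list (left) and the megakaryocyte list (right). Symbols are the 3 replicate arrays, the black bar is their mean and the grey band spans the floors of the arrays; 13 of 22 erythroid and 24 of 26 megakaryocyte genes lay above the floor on each array.

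The 2 globin genes above the floor were both embryonic. Hbb-y was at 13.03 ± 0.25 and Hbb-bh1 at 12.22 ± 0.64, of 6 measured globin genes. Both probe sets could share signal with near-identical globin copies, so the values are uncertain as gene identities. The adult Hbb-b2 was at 6.79 ± 0.07, below the floor on at least 1 array, and was above it with the floor at the 90th percentile or with the median over probe sets, which gave 3 globin genes. Also below the floor were the embryonic Hba-x at 5.43 ± 0.22 and the adult Hba-a2 and Hba-a1 at 5.81 ± 0.23 and 4.81 ± 0.15. The list held 9 genes, and Hbb-b1, Hbb-bs and Hbb-bt were not measured, so an absence of adult beta-globin was not shown. The heme and iron list had 14 of 16 measured genes above the floor. Its members included Fth1, the ferritin heavy chain, at 13.81 ± 0.08, and Tfrc, the transferrin receptor, at 11.98 ± 0.08. The heme synthesis enzymes Alad, Urod and Fech were at 11.48 ± 0.18, 11.41 ± 0.06 and 11.19 ± 0.05. Alas1, the first enzyme of the pathway in most cells, was at 7.94 ± 0.04. Alas2, the erythroid form of that enzyme, was at 5.89 ± 0.16, below the floor. With the median over a gene's probe sets in place of the brightest one, Tfrc read 8.87, Alad 9.53 and Urod 10.65. With the floor at the 99th percentile, 7 heme and iron genes were above it.

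Progenitor genes were also divided, with 12 of 23 above the floor. Etv6 was at 10.38 ± 0.15, the adhesion receptor Cd44 at 10.35 ± 0.02, the polycomb gene Bmi1 at 10.26 ± 0.07 and Myb, a regulator of progenitor growth, at 10.18 ± 0.08. With the median over probe sets, Etv6 read 9.31 and Cd44 9.20. Myc was at 10.01 ± 0.21 and Meis1 at 9.63 ± 0.04. Kit, the stem cell factor receptor, was below the floor at 5.45 ± 0.17, and so was Cd34 at 3.22 ± 0.12.

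Markers of other cell types lay mostly under the floor. None of the 18 measured lymphocyte genes, 10 embryonic stem cell genes or 14 endothelial and fibroblast genes was above it on each array, although 1 endothelial and fibroblast gene was with the median over probe sets. Pou5f1 and Nanog, factors of the embryonic stem cells from which the line was made, were at 4.11 ± 0.11 and 2.90 ± 0.17. Of 16 mast cell, basophil and eosinophil genes, Cpa3, a mast cell protease, was above the floor, at 7.45 ± 0.27, and none was with the floor at the 99th percentile. Of 18 granulocyte and macrophage genes 3 were above it, namely the lysozymes Lyz1 at 10.47 ± 0.16 and Lyz2 at 9.90 ± 0.25 and the Fc receptor gene Fcgr3 at 7.14 ± 0.08. The lysozyme genes are near-identical copies, so their signals cannot be separated with certainty, and Lyz1 read 9.06 with the median over probe sets. Mpo, Elane and Ctsg, which encode granule proteins of early myeloid cells, were at 5.39 ± 0.12, 4.93 ± 0.20 and 4.52 ± 0.03. Of the 48 measured background genes, 3 exceeded the floor, a count that a 95th percentile sets by construction. These were Cela1 at 10.09 ± 0.13, Ckm at 7.40 ± 0.25 and Krt10 at 6.95 ± 0.08. Such levels overlap those of genes counted here as above the floor, so that call does not by itself show expression.

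Genes of the dividing cell gave signal together with an inhibitor of division. Of 18 S phase genes 17 were above the floor, among them the replication clamp Pcna at 13.49 ± 0.05 and the helicase subunits Mcm7, Mcm6 and Mcm5 at 12.76 ± 0.09, 12.49 ± 0.02 and 12.27 ± 0.11. All 17 measured G2 and M phase genes were above it, with Cdc20 at 12.34 ± 0.09, Top2a at 11.79 ± 0.04, Ube2c at 11.57 ± 0.15 and Cdk1 at 11.57 ± 0.06. The cell cycle exit and survival list had 10 of 15 genes above the floor. Ccnd3, a G1 cyclin, was at 12.15 ± 0.03, Mcl1, a survival factor, at 11.77 ± 0.14, and the cyclin-dependent kinase inhibitors Cdkn1a and Cdkn2d at 11.31 ± 0.14 and 10.82 ± 0.14. With the median over a gene's probe sets in place of the brightest one, Top2a read 6.85, Ccnd3 7.49, Mcm7 11.56, Mcm6 10.83, Mcm5 11.30, Cdc20 11.76 and Mcl1 10.18, so the probe sets of these genes differed widely.

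Of 11 genes of the interferon response list 5 were above the floor, among them Oas1a at 10.14 ± 0.10, Irf9 at 8.08 ± 0.20, Ifit2 at 7.95 ± 0.08 and Ddx58 at 7.83 ± 0.08, while Ifit1, Irf7 and Mx1 were at 4.75 ± 0.08, 4.61 ± 0.24 and 3.70 ± 0.21. Ddx58 read 5.01, below the floor, with the median over its probe sets. Of 14 genes of the immediate early and stress list 7 were above it. With the floor at the 99th percentile, 1 gene of the interferon list and 2 of the stress list were above it. Asns, the asparagine synthetase, was at 11.74 ± 0.11, the early response factors Egr1 and Junb at 10.19 ± 0.39 and 8.50 ± 0.20, and Ier3 at 8.59 ± 0.07. All 12 measured housekeeping genes were above the floor, with Actb at 14.34 ± 0.06, Eef1a1 at 14.31 ± 0.01, Gapdh at 14.04 ± 0.08 and Rpl13a at 14.03 ± 0.03, which read 13.43 with the median over probe sets.

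The next question was how closely the replicates matched. Replicates 1 and 2 correlated across all 45101 probe sets at r = 0.997, and replicate 3 correlated with each of them at r = 0.995. These values are across probe sets, which are not independent replicates. The median SD of a gene above the floor was 0.0920 log2 units, and 95% of such genes had an SD under 0.254. A range over 1 log2 unit was seen in 586 of 45101 probe sets (1.3%), and in 50 without replicate 3. Of the 7863 genes above the floor, 29 had such a range. The outlying value was low in replicate 3 for 18 of them, low in replicate 2 for 7, high in replicate 2 for 3 and high in replicate 1 for 1.

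Among the genes above the floor, the largest range was that of Malat1, a long noncoding RNA of the nucleus, which read 12.51, 12.24 and 9.38 in replicates 1, 2 and 3. Ddx6, an RNA helicase of cytoplasmic granules, read 10.47, 10.20 and 7.90, while its other probe sets above the floor read 9.87, 9.61 and 7.63, and 9.33, 9.22 and 9.07. Runx1, a core factor of the megakaryocyte lineage, read 9.97, 9.91 and 8.58, and its other probe sets differed less. Otub1, a deubiquitinase, read 9.09, 8.76 and 7.76, and Epm2aip1 read 8.84, 8.80 and 7.56. Tubb3, a beta-tubulin, was highest in replicate 2, with 7.65, 8.76 and 7.17, as was Inpp4b, a lipid phosphatase, with 8.89, 9.51 and 8.08. Bnip3, a gene induced by low oxygen, was lowest in replicate 2, with 10.67, 9.97 and 11.28, as were Setd5, with 9.36, 8.09 and 8.98, and Chac1, a stress-induced enzyme of glutathione breakdown, with 8.61, 7.28 and 7.84. With the median over probe sets, the mean was 9.04 for Malat1, 8.93 for Ddx6, 8.27 for Runx1, 8.31 for Otub1, 7.40 for Epm2aip1, 6.53 for Inpp4b and 7.63 for Setd5.

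Small shifts of whole gene lists separated the arrays as well. The megakaryocyte list lay above its own mean by a median of 0.13 log2 units in replicate 2, where 18 of 24 genes were higher, and below it in replicate 3, at -0.10, where 17 of 24 were lower. Both values lay beyond all 10000 random lists of matched level. They shrank to 0.06 in replicate 2 without replicate 3, and to -0.04 in replicate 3 without replicate 2. The GATA1 partner list was at -0.13 in replicate 3, with 12 of 14 genes lower (percentile 0.02), and at 0.08 in replicate 1 (percentile 99.99). Without replicate 3 the shift in replicate 1 was -0.01, and without replicate 1 or 2 the shift in replicate 3 was -0.07 or -0.06. The S phase list was at -0.07 in replicate 2, with 14 of 17 genes lower (percentile 0.01), and at -0.04 without replicate 3. The immediate early and stress list was at 0.22 in replicate 1, with all 7 genes higher (beyond all random lists), and at -0.12 in replicate 2 (percentile 0.12). The first was 0.09 without replicate 2 and the second -0.21 without replicate 3. With no filter on dim genes the first was 0.13. After renewed quantile normalization the second was at -0.11 (percentile 0.63), no longer among the outermost 1% of random lists. The 2 embryonic globin genes had a median of -0.50 in replicate 2, while the erythroid list had a median of 0.00 there (percentile 51.5). In total 10 of 42 combinations of list and array lay among the outermost 1% of random lists, where lists drawn at random would give 0.42. Lists of genes that vary together can exceed that number. The 3 deviations of 1 list sum to about 0 and some lists share genes, so these combinations are not independent.

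**Figure D2:**
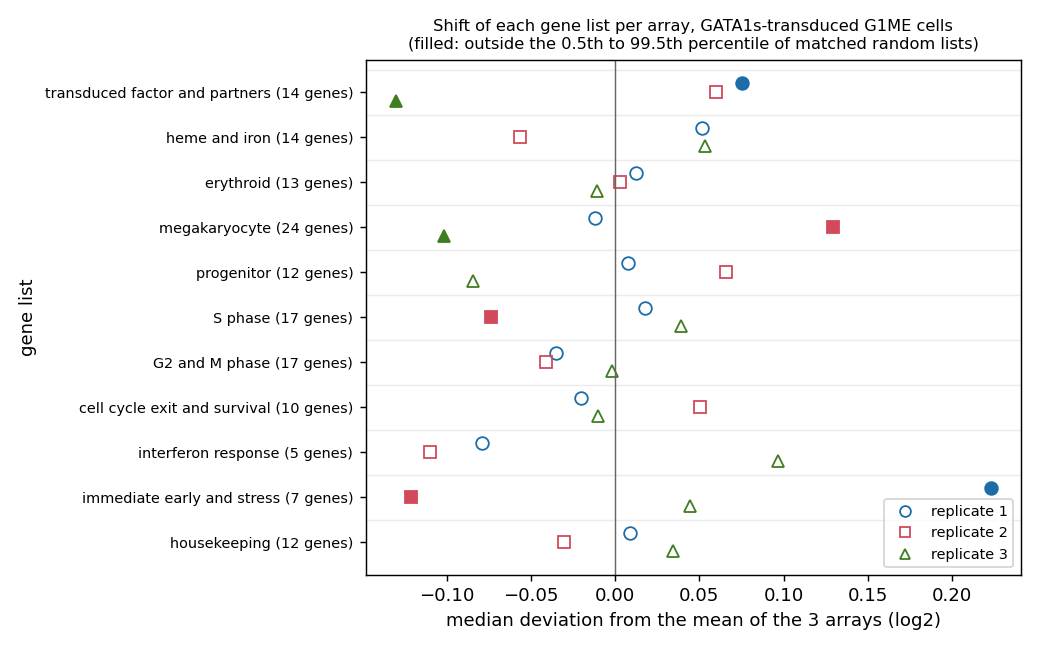
Median deviation of each gene list from the mean of the 3 arrays in log2 units (horizontal axis), for the lists with 5 or more genes above the floor; symbols are the replicates and filled symbols lie among the outermost 1% of matched random lists. The megakaryocyte list reached 0.13 in replicate 2 and -0.10 in replicate 3, and the immediate early and stress list 0.22 in replicate 1.

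Control probe sets gave a measure of RNA quality beside these differences. The signal at the 5' end minus that at the 3' end of the transferrin receptor transcript was -0.86, -0.94 and -1.003 log2 units in replicates 1, 2 and 3. For beta-actin it was -0.09, -0.16 and -0.23, and for Gapdh 0.06, 0.08 and 0.12. Signal from 18S ribosomal RNA differed more. Its 5' probe set read 10.09, 11.63 and 5.93, its middle one 7.14, 8.45 and 6.20 and its 3' one 8.44, 9.54 and 7.97. The 5' minus 3' difference was 1.65, 2.09 and -2.05. In replicate 3 the 5' and middle probe sets read below the floor of 6.92, so the size of the -2.05 is uncertain. No difference between the replicates was tested against another group, since the samples form 1 group.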

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

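Leaving out each replicate in turn, or reading the other table, moved no count of genes above the floor by over 1.5 times, for the full set or for any of the 17 lists. The floor itself mattered most. At the 99th percentile, 4164 genes were above it in place of 7863, the erythroid list fell from 13 to 6, the heme and iron list from 14 to 7, the interferon list from 5 to 1, the stress list from 7 to 2 and the mast cell list from 1 to 0; the 99th percentile rests on the brightest background gene, Cela1, and leaving it out at the 95th percentile (an alternative chosen after seeing the data) moved no list by over 1.5 times. The number of probe sets with a range over 1 log2 unit was 586. It lay between 50 and 441 with a replicate left out, the 50 being without replicate 3, and was 127 among probe sets above the floor. With a limit of 0.5 log2 units it was 3497. Renewed quantile normalization gave 562, and took the stress list in replicate 2 from -0.12 to -0.11, out of the outermost 1% of random lists. The shift of the GATA1 partner list in replicate 1 turned from 0.0755 to -0.00963 without replicate 3 and was 0.0647 without replicate 2. Without replicate 3, replicates 1 and 2 barely differed in this list (-0.00963 and 0.00963). The shift in replicate 1 therefore rested on the low replicate 3, at -0.13, and is no shift of its own. Why replicate 3 was low in this list was not tested. Of the other shifts among the outermost 1%, over lists with at least 5 genes, none changed sign in the alternatives run. Several shrank with a replicate left out, which also moves the mean they are taken from. With no filter on dim genes the stress list in replicate 1 fell from 0.22 to 0.13. The median over probe sets took the endothelial and fibroblast list from 0 to 1 and moved 27 of 59 named levels by over 1 SD. Many of the 59 genes, such as Gata1 and Pf4, have only 1 probe set and could not move, so 27 of 59 understates the dependence on the probe set. With 3 arrays and signals near the floor compressed by RMA, a gene below the floor cannot be called silent. The comparison with full-length GATA1 and its alternatives were not run. No paired analysis was possible because the samples form 1 group.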

Other observations

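The patterns in this part were seen first and then tested on the same arrays, and the tests of RNA degradation and of other probe sets, in their form here, were chosen after the values they use had been seen. The genes named here were also chosen after their values were seen. A second list of megakaryocyte genes, sharing none with the first, had 20 of 28 measured members above the floor. It included Fermt3, an adaptor that activates integrins, at 13.36 ± 0.07 (SD, n = 3), Lat, an adaptor of platelet collagen signalling, at 12.25 ± 0.06, and the cytoskeletal genes Zyx, Tln1 and Vcl at 12.23 ± 0.19, 12.15 ± 0.27 and 11.74 ± 0.24. Angpt1, which encodes a ligand of the endothelial receptor Tek, was at 9.94 ± 0.19. A hypoxia list had 22 of 27 members above the floor, with the glucose transporter Slc2a3 at 13.40 ± 0.002 and the glycolytic genes Ldha and Aldoa at 13.32 ± 0.08 and 13.15 ± 0.08. A list of ATF4 target genes, which respond to amino acid shortage, had 25 of 28, with Psat1 and Phgdh of serine synthesis at 11.93 ± 0.08 and 11.23 ± 0.05.

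The second megakaryocyte list repeated the shift of the first, with a median of 0.12 log2 units and 19 of 20 genes higher in replicate 2 (percentile 100), and -0.13 with 17 of 20 lower in replicate 3. The hypoxia list went the other way, with -0.13 and 19 of 22 genes lower in replicate 2 (percentile 0), and 0.11 with 20 of 22 higher in replicate 3. Other measures parted the same arrays. The 5' probe set of 18S ribosomal RNA read 10.09, 11.63 and 5.93 in replicates 1, 2 and 3. The middle one read 7.14, 8.45 and 6.20, and the 3' one 8.44, 9.54 and 7.97. A list of nuclear-retained and slowly exported transcripts lay at 0.07 in replicate 2 (percentile 99.95) and at -0.07 in replicate 3. Array-wide scaling could not be tested, since the values had been quantile normalized. A larger megakaryocyte program and a weaker hypoxia response in replicate 2 would both give such list values, as hypotheses only. So would a smaller megakaryocyte program and a stronger hypoxia response in replicate 3. Replicate 1 lay between, at -0.01 for the second megakaryocyte list and 0.01 for the hypoxia list, so neither array was shown to be the odd one. A difference in RNA fraction between the arrays was not excluded.

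Malat1 and 17 further genes were low in replicate 3, with a median difference of -1.10 log2 units from the mean of the other arrays. These 18 genes were picked for a range over 1 log2 unit with the outlying value low in replicate 3. A large median difference was therefore set by that choice. Their other probe sets were not picked in this way and could differ less for that reason. RNA degradation stays open. In replicate 3 the 5' minus 3' difference of the transferrin receptor control was lower than the mean of the other arrays by a small amount (-0.10). The difference was lowest in replicate 3 for beta-actin (-0.09, -0.16 and -0.23) and for 18S ribosomal RNA (1.65, 2.09 and -2.05), but highest there for Gapdh (0.06, 0.08 and 0.12). The 5' probe set of 18S read 5.93 in replicate 3, below the floor of 6.92, so the size of the 18S difference is uncertain. Faulty single probe sets are argued against for Malat1, because its 5 other probe sets with a mean above the floor were also lower, with differences of -3.35 to -1.34 (median deviation from their own mean -1.10). For the whole set they stay open. The 26 other probe sets of 13 of the genes deviated from their own mean by a median of -0.20, with 24 lower (-0.17 or -0.21 under other rules for the floor). On the measure used for the 18 genes, the difference from the mean of the other arrays, their median was -0.29. Outside Malat1 the median deviation from their own mean was -0.14, with 19 of 21 lower. Of these 21, 1, of Ddx6, was lower than the mean of the other arrays by over 1. A lower yield of nuclear-retained transcripts was set against a list of 23 nuclear-retained and slowly exported transcripts. In replicate 3, 16 of them were lower and 7 higher than their own mean (percentile 0.54). That list was at -0.07 there, far less than Malat1, and at 0.07 in replicate 2 (percentile 99.95), so it may bear on the direction only.

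The stress list was high in replicate 1. Its members included Egr1, an early response gene, at 10.59 against 10.16 and 9.81, Chac1 at 8.61 against 7.28 and 7.84, and Asns at 11.78 against 11.62 and 11.82, the last in replicate 3. Array-wide scaling could not be tested there either, and no other technical explanation was tested. The ATF4 list lay at 0.06 in replicate 1 with 19 of 25 genes higher (percentile 99.97). It shared no gene with the stress list only because members of the earlier lists had been left out of it. Both lists were read on the same arrays, so the ATF4 list is no independent evidence. An amino acid response in replicate 1 could be one part of the shift of the stress list, as a hypothesis only. In replicate 2 the ATF4 list lay at -0.05 with 18 of 25 genes lower (percentile 1.15), so a high replicate 1 and a low replicate 2 were not told apart. The 0.06 is smaller than the 0.22 of the stress list, so the rest stays open. That 0.22 was 0.13 with no filter on dim genes and 0.09 without replicate 2, so the size of the rest is uncertain.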
